A study of Mus musculus with 40 samples.

How the data were processed

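RNA was measured by sequencing in tumor-associated macrophages (TAM), monocytic myeloid-derived suppressor cells (MDSC) and whole tumors of mice carrying MC38 tumors. Per the labels' protocols, treatment began when tumors reached about 250 mm3, with 4 mice per group, while the series' design text gives a larger number. Anti-CD40 was given once, on day 11. Per the same protocols, 1 ng of amplified cDNA entered each library, made with the Nextera XT kit, and both ends of each fragment were read for 50 cycles on a HiSeq2500. The labels do not say which library came from which mouse, nor whether TAM and MDSC libraries came from the same tumors. The p-values therefore measure the spread between these libraries, which may in part be technical. The labels give no replicate numbers, so replicates were numbered in the order of their records and no pairing was used. If TAM and MDSC libraries share tumors, the fits over both populations leave that out. The titles carry library codes in 2 forms, with and without an N index, which are not balanced over the groups.

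The authors deposited 1 table per library with Ensembl gene identifiers, and each holds 3 kinds of values. The unique read counts are raw counts of reads placed at a single site, per the file headers. All values of this column were even in all 40 libraries, so both mates of a pair were counted and the number of fragments is lower than the number of reads. The counts with shared reads are estimated counts in which reads with several sites are shared out in parts, per the file headers. The authors also deposited RPKM values, whose gene lengths and read total are not given in the sources used here. Bowtie2 is named in the submitters' processing notes with no version. The genome build, the annotation, the counting program and its filters are not given in the sources used here. Whether the counting used strand is not given either, so reads of overlapping and antisense genes cannot be told apart, and paralogs can lose reads in the unique counts.

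Of 28929 Ensembl identifiers, 25762 were named by Ensembl identifier and 261 by Entrez identifier, and 2906 had no symbol. The reference tables put 4 symbols on more than 1 identifier. Coordinates of Csf1r and Cd40 come from the GRCm38 annotation supplied with the data, which may not be the build the authors used. Libraries held between 32445164 and 60572316 unique reads, counted over genes. CPM values are per 1e6 effective reads after TMM scaling within each fit. Without molecular identifiers reads are not independent molecules. Both mates of a pair were counted, so the floor of 3 reads per library is lower than 3 fragments and does not fully cover counting error. A floor of 3 fragments would give smaller folds for genes without reads in a group.

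All adjusted p-values of genes are from edgeR 4.0.16 in R 4.3.3, unless another tool is named. Its quasi-likelihood test was run on the unique counts with TMM scaling, edgeR's own filter on low counts by group, and Benjamini-Hochberg adjustment with a threshold of 0.05. Among genes without change, chance alone gives an unadjusted p under 0.05 in a share of about 0.05. All 16 TAM libraries were fitted together, all 16 MDSC libraries together and the 8 whole tumor libraries together. All 32 sorted libraries were fitted jointly for TAM against MDSC and for the differences in response between them. In each sorted population the contrasts were each treatment against IgG, the combination against each single antibody, and the interaction of the antibodies, which made 17 contrasts in all. Values are mean CPM ± SD over 4 libraries, and log2 changes are given ± SE. For genes without reads in a group the fold is given against the floor of 3 reads per library, here called the bound.

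A total of 31 gene lists was tested. They were inflammatory cytokines, chemokines, type I interferon response, interferon-gamma response, MHC class II presentation, MHC class I presentation, costimulation and maturation, NF-kappaB targets, alternative macrophage activation, immune suppression and checkpoints, matrix remodelling and angiogenesis, mature macrophage, monocyte, neutrophil, dendritic cell, T and NK cell, B cell, epithelial tumor cell, fibroblast and endothelium, proliferation, cell death, immediate early and dissociation response, glycolysis and hypoxia, oxidative phosphorylation, lysosome, cholesterol synthesis, cholesterol efflux and LXR targets, endoplasmic reticulum stress, oxidative stress response, mitochondrially encoded and ribosomal proteins. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the lists of a contrast. Each list was also tested with an estimated correlation and with fry, a rotation test of the list alone. The B cell list had too few tested members in MDSC, and the mitochondrially encoded list had 0 tested members in every fit. Counts adjusted over the list alone use Benjamini-Hochberg adjustment over the members of that list.

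The genes named in the text follow a rule in 3 parts. The first part takes up to 6 called genes with the largest increase and up to 6 with the largest decrease, whose groups do not overlap and whose mean log2 CPM is at least 3, without provisional symbols, immunoglobulin or T cell receptor segments and small RNAs. For genes taken by this part non-overlap is thus a condition and not a result. Non-overlap is not asked of interactions and differences in response. The second part takes from each list up to 4 tested members with the smallest p, called or not. The third part is a fixed set of genes, Csf1r, Cd40, Csf1, Adgre1, Ly6c2, Itgam, Tnf, Il12b, Il6, Il1b, Il10, Cd274, Arg1, Nos2, Cxcl9, Cxcl10, Ccl5, H2-Ab1, Cd86 and Mrc1. Not all genes that the rule takes are named, and some results are not reported here. Ahrr, Ltbp2, Pcdhb5 and 1700028J19Rik, and the values of Flt3, Ccr7, Ccl22 and Zbtb46 in single MDSC IgG libraries, fall outside it and were chosen after their values were seen. The groups, contrasts, tests, lists, naming rule and the first set of other settings were set before the data were examined.

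Other settings set beforehand were size factors of DESeq2 (RLE) within edgeR, DESeq2 1.42.0, voom with quality weights in limma, no count filter other than 1 read, a filter of at least 5 CPM in at least 4 libraries, only the groups compared in the fit, the title code form as a covariate, limma on log2(RPKM + 1), and each library left out in turn. For the RPKM test genes were those passing the edgeR filter on counts. Settings meant only for files without counts did not apply. Settings chosen after seeing the data were leaving out TAM IgG 1 and MDSC IgG 1, which were rich in ribosomal RNA, leaving out MDSC IgG 1 and 2, whose Ly6c2 was low, halving the counts to read pairs, using the counts with shared reads rounded to whole numbers, using protein-coding genes outside the mitochondrion, and repeating the list tests without single libraries or the libraries rich in ribosomal RNA.

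The code was tested on simulated counts drawn from the real means, library sizes and spread, with 200 genes changed by known folds. For TAM combination against IgG (17055 genes) it recovered 2.04% of genes changed 2-fold, 39.6% of those changed 4-fold, 65.3% at 8-fold and 71.7% at 16-fold. For the same contrast in MDSC (17319 genes) these shares were 6.25%, 46.9%, 50% and 64.6%, and for whole tumors (17206 genes) 42.6%, 93.8%, 89.1% and 95.7%. For the difference in response to the combination (18473 genes) they were 0%, 16.3%, 28.6% and 37.5%. Of the genes called, 3 of 90, 7 of 87, 5 of 164 and 3 of 43 were unchanged, in the same order of contrasts. A planted list of 21 genes was called upward in each of these 4 contrasts and 0 other lists were. Simulated genes were drawn independently of each other. The simulation therefore cannot show how often list tests make false calls where genes are correlated.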

Results

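The data were 40 RNA-seq libraries from MC38 tumors, a mouse colorectal adenocarcinoma line grown under the skin of female C57BL/6N mice. Mice received an antibody against the colony-stimulating factor 1 receptor (anti-CSF-1R, clone 2G2, 30 mg/kg), an agonist antibody against the costimulatory receptor CD40 (anti-CD40, 4 mg/kg), both antibodies, or control immunoglobulin (IgG). Tumors were taken 16 h after treatment. Tumor-associated macrophages (TAM) and monocytic myeloid-derived suppressor cells (MDSC) were sorted by flow cytometry, TAM as F4/80-high and Ly6C-low cells and MDSC as F4/80-negative or low and Ly6C-high cells. Each population gave 4 groups of 4 libraries, and whole tumors gave 4 IgG and 4 anti-CSF-1R libraries. The libraries held 32445164 (MDSC IgG 1) to 60572316 (TAM combination library 2) uniquely placed reads.

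TAM IgG 1 and MDSC IgG 1 were the shallowest libraries, at 33095944 and 32445164 reads, and held the largest shares of ribosomal RNA reads, at 12.02% and 31.9%. Every other library lay between 0.271% and 2.11%. The lowest pairwise correlation of log CPM across genes within a group was 0.786 in MDSC IgG and 0.856 in the MDSC combination group. It was 0.929 and 0.937 in MDSC after anti-CSF-1R and anti-CD40. The lowest value was 0.893 or more in each TAM group and 0.923 or more in each group of whole tumors. Ly6c2, which encodes the Ly6C antigen of the sort gate, stood at 35.8 CPM in MDSC IgG 1 and 48.6 CPM in MDSC IgG 2, against 1582 and 1272 CPM in MDSC IgG 3 and 4. Every comparison with the MDSC IgG group includes these libraries.

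**Figure D1:**
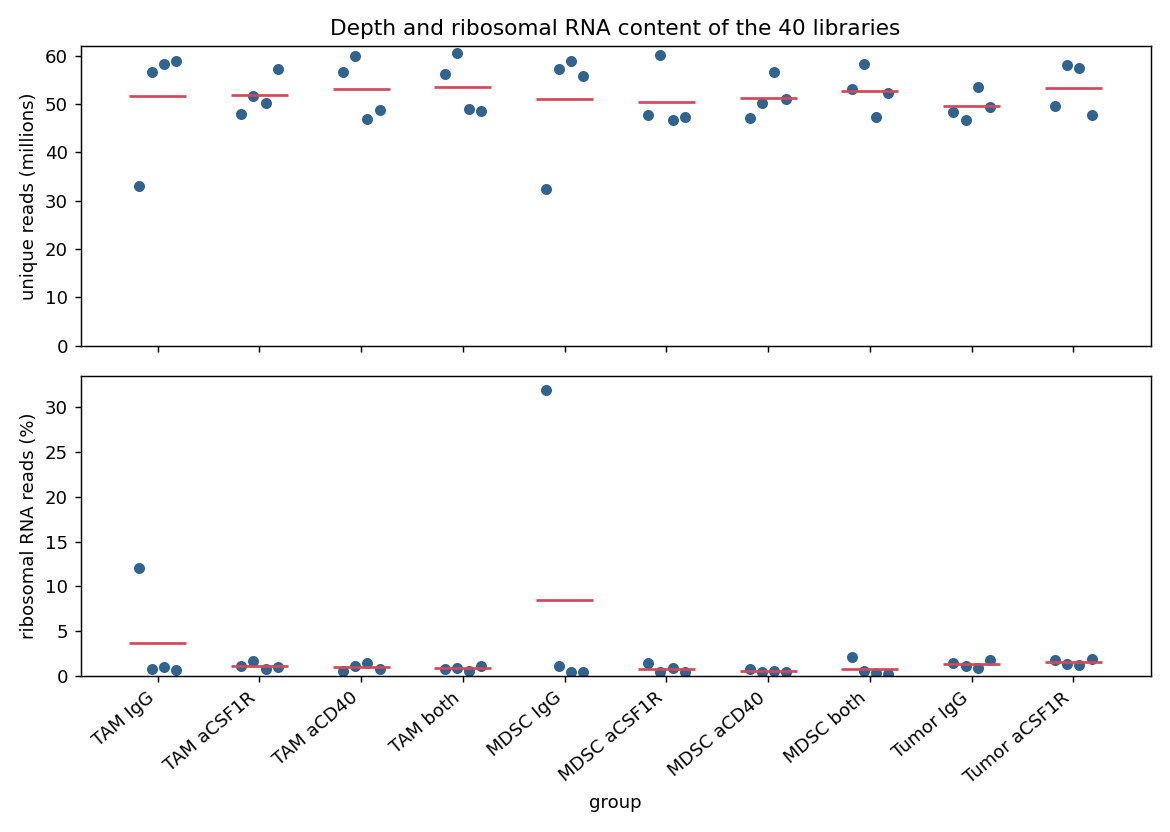
Uniquely placed reads, on an axis in units of 1e6 reads (upper panel), and ribosomal RNA reads in percent (lower panel) for each of the 40 libraries, by group, where each point is a library and each bar the mean of 4. TAM IgG 1 (33095944 reads, 12.02%) and MDSC IgG 1 (32445164 reads, 31.9%) stand apart from the rest.

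Both antibody targets were expressed in the sorted cells. Csf1r (ENSMUSG00000024621; chromosome 18, 61100598 to 61132149, plus strand, in the GRCm38 annotation) averaged 1448 ± 686 CPM in TAM IgG (SD, n = 4) and 1341 ± 664 CPM in MDSC IgG. Its log2 change after anti-CSF-1R was 0.63 ± 0.43 (SE) in TAM, 0.18 ± 0.45 in MDSC and -0.07 ± 0.40 in whole tumors, none past the threshold (adjusted p = 1 in each). Its sign turned in MDSC without MDSC IgG 1 (-0.06), and in whole tumors without IgG library 3 (0.15) or anti-CSF-1R library 4 (0.24), and the whole tumor value was 0 without anti-CSF-1R library 3. TAM IgG 1 had Csf1r at 439 CPM against 1651 to 1965 CPM in the other TAM IgG libraries. Cd40 (ENSMUSG00000017652; chromosome 2, 165055627 to 165072948, plus strand) averaged 90.5 ± 19.3 CPM in TAM IgG. It rose in TAM after both antibodies, by 2.29 ± 0.42 on the log2 scale to 444 ± 242 CPM (adjusted p = 0.0181), with combination libraries 1, 2 and 3 above every IgG library and library 4 within the IgG range. This call was lost without TAM IgG 2, 3 or 4 and without combination library 1, 2 or 3 (adjusted p = 0.0532 to 0.108). The antibodies bind the proteins, so these transcript levels do not measure target blockade.

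In IgG-treated mice, TAM carried more transcript of macrophage genes than MDSC, and MDSC more of monocyte genes. Ms4a7, a macrophage membrane protein, was higher in TAM (log2 difference 2.58 ± 0.46, adjusted p = 0.00563), as were the mannose receptor Mrc1 (2.32 ± 0.47, adjusted p = 0.0158), the folate receptor Folr2 (4.29 ± 0.88, adjusted p = 0.0178) and the chemokine Ccl8 (3.85 ± 0.80, adjusted p = 0.0185). Ly6c2 was lower in TAM (-5.64 ± 0.86, adjusted p = 0.0017), with Plac8 (-4.89 ± 0.70, adjusted p = 0.00102). The peptidase Dpp4, a member of the dendritic cell list, was lower too (-3.01 ± 0.58, adjusted p = 0.00916). For each of these genes all 4 libraries of the higher population lay above all 4 of the other, which the naming rule asks of genes of largest change. Over all genes tested 5.185% were so separated, against 2.857% by chance. Of the genes tested, 131 of 18921 passed, 69 higher and 62 lower in TAM. Adgre1, the gene of the F4/80 antigen, stood at 1049 ± 534 CPM in TAM and 315 ± 129 CPM in MDSC (adjusted p = 0.139). Ahrr, a repressor of the aryl hydrocarbon receptor, had no reads in the MDSC IgG libraries. It was 37.95-fold higher in TAM against a floor of 3 reads per library. It was chosen after its values were seen. With the 8 IgG libraries fitted alone 1 gene passed, and every gene named here as higher or lower lost its call, at adjusted p of 0.162 to 0.315. Without the MDSC IgG libraries of low Ly6c2, 236 genes passed and Folr2 did not (adjusted p = 0.0615). The count was 38 without TAM IgG 3, where Ccl8 (adjusted p = 0.0723) and Dpp4 (0.0512) were lost, and 77 without MDSC IgG 3, where Ccl8 (0.0528) and Mrc1 (0.0563) were lost. It was 52 without TAM IgG 2, 52 without TAM IgG 4, where Mrc1 was lost (adjusted p = 0.0536), and 229 without MDSC IgG 2.

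Among the cell type lists, mature macrophage genes were higher in TAM than in MDSC (3 of 21 members, 15 adjusted over the list alone, median log2 difference 1.55, adjusted p = 0.0112 with an estimated correlation). Monocyte genes were lower (6 of 16 members, with 10 lower and 1 higher adjusted over the list alone, median -1.52, adjusted p = 0.0170 with an estimated correlation), as were neutrophil genes (2 of 17, 7 adjusted over the list alone, median -2.23, adjusted p = 0.00652 with an estimated correlation). Dendritic cell genes were lower (3 of 15, 7 adjusted over the list alone, median -2.47, or -1.86 with a member without reads at its bound, adjusted p = 0.00328 with an estimated correlation). The dendritic cell growth factor receptor Flt3, chosen after its values were seen, stood at 38.7 and 14.9 CPM in MDSC IgG 1 and 2 and at 4.62 and 0.805 CPM in MDSC IgG 3 and 4. T and NK cell genes (median -1.16, 0 of 23, 12 lower adjusted over the list alone), fibroblast and endothelium genes (-1.44, 0 of 20, 0 alone), lysosome genes (0.75, 2 of 25, 7 alone) and alternative activation genes (1.01, 2 of 18 higher and 1 lower, 5 higher and 1 lower alone) were called and lost at adjusted p = 0.163 in each with an estimated correlation. The epithelial tumor cell list (1 higher and 1 lower of 13) was called lower (median -0.87, adjusted p = 0.0289) although its mean was 0.08, and was lost at adjusted p = 0.177 with an estimated correlation. Without the MDSC IgG libraries of low Ly6c2 the fitted median was -1.27 for dendritic cell genes (adjusted p = 0.000893), -1 for neutrophil genes (4.15e-05, and -1.47 without MDSC IgG 1 alone) and 1.77 for alternative activation genes (0.00505), and the epithelial tumor cell call was lost (median 0, adjusted p = 0.149).

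After both antibodies, TAM carried more transcript of Il12b and maturation genes than after IgG, and less of the mannose receptor. Il12b, a subunit shared by interleukin-12 and interleukin-23, rose from 8.09 ± 3.71 to 2651 ± 2119 CPM (SD, n = 4; log2 change 8.36 ± 1.17, adjusted p = 0.00612). The chemokine Ccl22 rose by 8.64 ± 1.31 (adjusted p = 0.0115), the lymph node homing receptor Ccr7 by 7.87 ± 1.27 (adjusted p = 0.0125) and the T cell chemokine Ccl5 by 3.48 ± 0.46 (adjusted p = 0.00612). Mrc1 fell from 374 ± 125 to 67.9 ± 25.3 CPM (-2.46 ± 0.38, adjusted p = 0.0123), and the creatine kinase Ckb fell too (-2.49 ± 0.40, adjusted p = 0.0125). For each of these 6 genes all 4 combination libraries lay on one side of all 4 IgG libraries, which the naming rule asks of genes of largest change. Over all genes tested 5.361% were so separated, against 2.857% by chance. In edgeR's quasi-likelihood test 117 of 17571 genes passed, 98 higher and 19 lower. Without TAM IgG 4 no gene passed, and these 6 genes stood at adjusted p of 0.0606 to 0.0815. Ccr7 was also lost without TAM IgG 2 (adjusted p = 0.0527) and Ckb without combination library 3 (0.0521).

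Costimulation and maturation genes rose in TAM after both antibodies (4 of 17 members, 9 adjusted over the list alone, median 1.94, adjusted p = 0.0477 with an estimated correlation). Among them, Il15ra, which presents interleukin-15, rose by 2.79 ± 0.45 (adjusted p = 0.0125), a call lost without TAM IgG 2 (0.0527) or 4 (0.0737). Type I interferon response genes rose (2 of 28, 23 adjusted over the list alone, all 28 with positive log2 changes, median 1.14, adjusted p = 0.0373 with an estimated correlation). Rsad2, an antiviral enzyme, rose by 1.92 ± 0.36 (adjusted p = 0.0202), lost without TAM IgG 2, 3 or 4 and without combination library 1, 2 or 3 (adjusted p = 0.0506 to 0.115). Alternative activation genes fell (2 of 18, 10 adjusted over the list alone, median -1.48, adjusted p = 0.0373 with an estimated correlation), and all 18 had negative log2 changes. Inflammatory cytokine genes had a median of 1.5 (2 of 17, 7 adjusted over the list alone), called and lost at adjusted p = 0.0869 with an estimated correlation. The inducible nitric oxide synthase Nos2 rose by 3.64 ± 0.71 (adjusted p = 0.0223), lost without any 1 of the TAM IgG libraries and without combination library 1, 2 or 3 (adjusted p = 0.0559 to 0.116). In Il15ra, Rsad2 and Nos2 all 4 combination libraries lay above all 4 IgG libraries. Il10 stood at 15.9 ± 6.69 CPM against 46.4 ± 29.2 CPM in IgG and did not pass (adjusted p = 0.186).

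T and NK cell genes rose in the sorted TAM libraries after both antibodies (4 of 23, 12 adjusted over the list alone, median 1.03, adjusted p = 0.0373 with an estimated correlation). The called members included the cytotoxic granule genes Gzmb (2.06 ± 0.35, adjusted p = 0.0139) and Gzma (1.85 ± 0.31, adjusted p = 0.0129) and the T cell coreceptor Cd8a (1.78 ± 0.33, adjusted p = 0.0189), each higher in 4 of 4 libraries than in any IgG library. Cd8a averaged 17.4 ± 5.36 CPM and Gzmb 95.9 ± 35.3 CPM. Gzmb was lost without TAM IgG 2 (adjusted p = 0.0527), TAM IgG 4 (0.1) or combination library 3 (0.0523), Gzma without TAM IgG 4 (0.0815) or combination library 3 (0.0523), and Cd8a without TAM IgG 2, 3 or 4 or combination library 1 (0.0562 to 0.104). Oxidative stress genes rose (1 of 15, 3 adjusted over the list alone, median 0.44, adjusted p = 0.0373 with an estimated correlation). Their called member, the cystine transporter Slc7a11, rose by 2.32 ± 0.48 (adjusted p = 0.0316), with combination libraries 1, 2 and 3 above every IgG library and library 4 within their range. It was lost without TAM IgG 2, 3 or 4, anti-CSF-1R library 2 or 3, or combination library 1, 2 or 3 (adjusted p = 0.0562 to 0.153), and by limma on RPKM (0.0697).

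Further lists were called in TAM after both antibodies with the preset correlation and lost with an estimated one. Proliferation genes had a median of -0.70 (0 of 30 called, 0 adjusted over the list alone) and glycolysis and hypoxia genes 0.64 (0 of 23, 8 adjusted over the list alone), lost at adjusted p = 0.156 and adjusted p = 0.0838 with an estimated correlation. NF-kappaB targets (median 0.92, 1 of 26, 5 adjusted over the list alone), interferon-gamma response (0.54, 2 of 23, 5 alone) and MHC class I presentation (0.45, 0 of 16, 3 alone) were called upward and lost at adjusted p = 0.226, 0.156 and 0.156 with an estimated correlation. Chemokines (0.46, 3 of 26, 6 higher and 1 lower alone) and monocyte genes (0.46, 1 of 16, 3 higher and 1 lower alone) were lost at adjusted p = 0.291 and 0.156 with an estimated correlation. MHC class II presentation (0.35, 1 of 11, 1 alone), cell death (0.26, 1 of 22, 3 alone), mature macrophage (-0.39, 0 of 21, 4 lower alone) and ribosomal protein genes (-0.23, 0 of 30, 0 alone) were lost at adjusted p = 0.500, 0.109, 0.271 and 0.642 with an estimated correlation. Without TAM IgG 1, rich in ribosomal RNA, the mature macrophage median was -0.63 (adjusted p = 4.95e-10). The calls of MHC class II presentation (median 0.13, adjusted p = 0.725), monocyte (0.53, 0.118), cell death (0.38, 0.0634) and ribosomal protein genes (-0.17, 0.101) were then lost, and 2 other lists gained one.

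The lists not called in TAM after both antibodies, by median log2 change, were neutrophil (0.50), dendritic cell (0.28, or 0.38 with a member without reads at its bound), B cell (0.44, also with a member at its bound), epithelial tumor cell (-0.63), fibroblast and endothelium (0.03), immediate early and dissociation response (-0.11), oxidative phosphorylation (-0.15), lysosome (0.17), cholesterol synthesis (0.07) and cholesterol efflux and LXR targets (0.07). Of these, fibroblast and endothelium held 1 called gene of 19 and the others 0. Adjusted over the list alone, dendritic cell held 1 gene higher and 2 lower, epithelial tumor cell 1 lower, fibroblast and endothelium 1 higher, LXR targets 1 higher and the rest 0. Without TAM IgG 1, fibroblast and endothelium genes were called upward with the preset correlation (median 0.92, adjusted p = 0.0112) and oxidative phosphorylation genes downward (-0.11, 0.046), and the medians of B cell and neutrophil genes were 0.96 (0.0635) and 0.71 (0.0634). Median and mean differed in sign for immune suppression and checkpoints (-0.22 and 0.68, tested upward, 2 called genes of 16, with 4 higher and 2 lower adjusted over the list alone). They also did for matrix remodelling and angiogenesis (0.09 and -0.09, tested downward) and endoplasmic reticulum stress (-0.17 and 0.02, tested downward), which held 0 called genes and 0 adjusted over the list alone. The mitochondrially encoded list had no member among the genes tested.

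The 4 TAM libraries of both antibodies were not alike. Combination libraries 1, 2 and 3 held Ccl22 at 1581 to 2991 CPM and library 4 at 46.1 CPM, and Ccr7 ran from 3034 to 3801 CPM against 73.4 CPM. The count of 117 was 0 without TAM IgG 4, 11 without TAM IgG 2, 23 without combination library 3, 27 without library 1, 37 without TAM IgG 3, 39 without combination library 2, 249 without anti-CD40 library 3 and 565 without combination library 4. With the IgG and combination libraries fitted alone no gene passed, and the genes named as called stood at adjusted p of 0.0551 to 0.124. DESeq2 called 544 genes, limma's voom with quality weights 1372, and edgeR 209 with the form of the title code as a covariate.

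**Figure D2:**
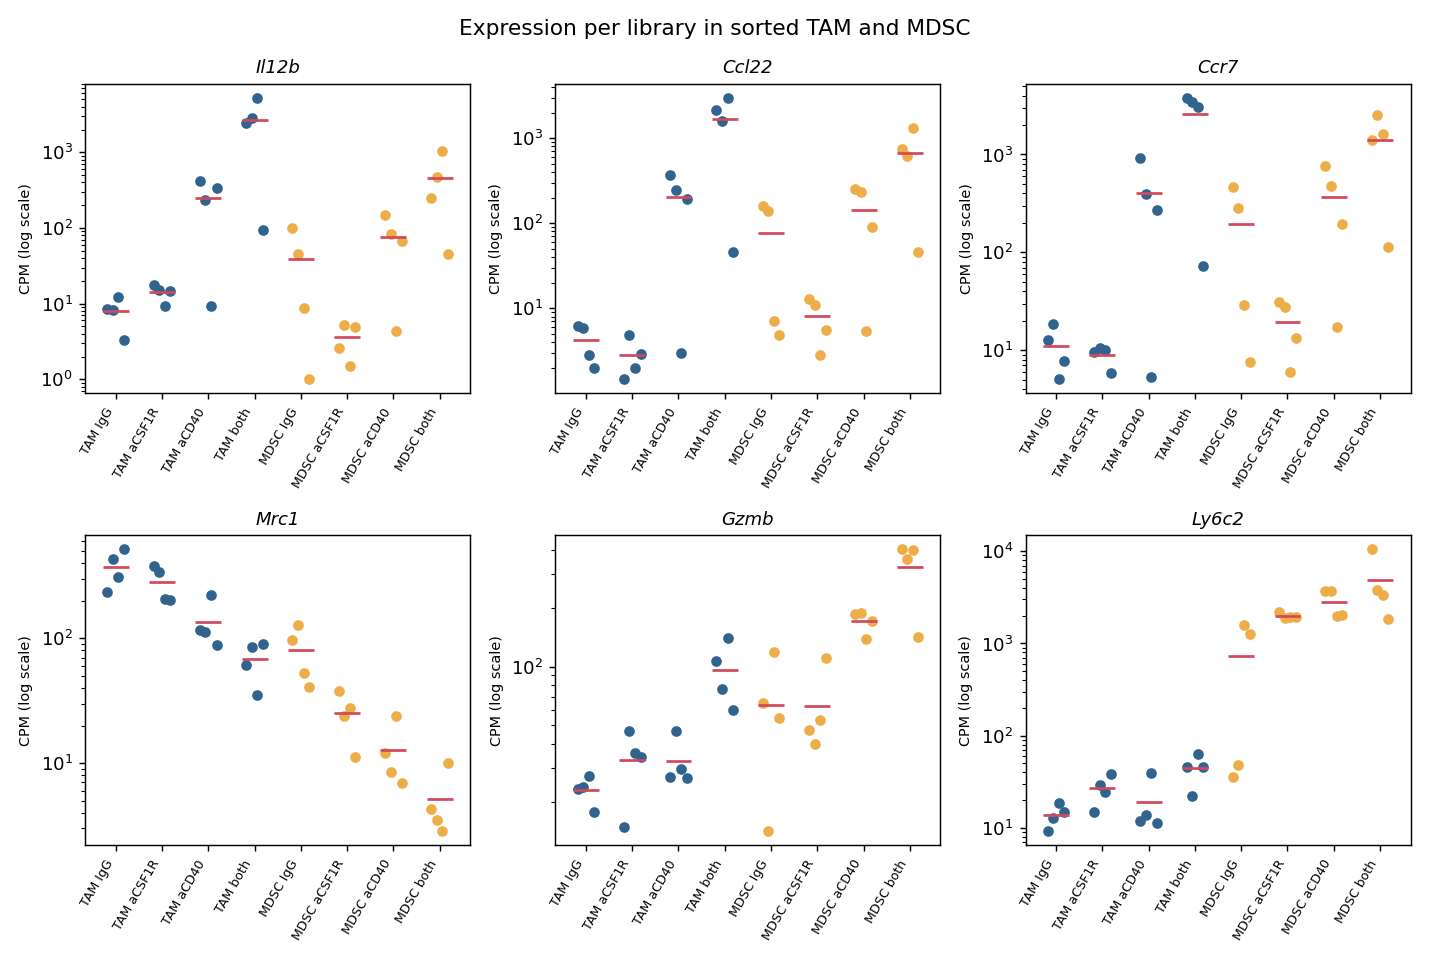
CPM on a log scale of Il12b, Ccl22, Ccr7, Mrc1, Gzmb and Ly6c2 in each library of sorted TAM (blue points) and MDSC (orange points), with red bars at the arithmetic mean of 4 libraries. In TAM after both antibodies, Ccl22 lies between 1581 and 2991 CPM in 3 libraries and at 46.1 CPM in the fourth, and Ly6c2 of MDSC IgG 1 and 2 lies at 35.8 and 48.6 CPM.

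After anti-CD40 alone, type I interferon genes rose in TAM (median 1.04, 16 of 28 adjusted over the list alone and 0 over all genes, adjusted p = 8.4e-28, and adjusted p = 0.0428 with an estimated correlation). Il12b averaged 252 ± 179 CPM against 8.09 ± 3.71 in IgG (log2 change 4.96 ± 1.00, adjusted p = 0.187), Ccl22 201 ± 151 against 4.23 ± 2.13 (adjusted p = 0.187) and Ccr7 400 ± 388 against 11.0 ± 5.97 (adjusted p = 0.215), none past the threshold. Library 3 of this group held Il12b at 9.27 CPM and Ccl22 at 2.97 CPM, against 235 to 422 and 193 to 365 CPM in the other 3. Costimulation and maturation genes (median 0.63, 0 of 17 over all genes and 2 adjusted over the list alone) and alternative activation genes (-0.68, 0 of 18 and 1 adjusted over the list alone) were called and lost at adjusted p = 0.472 and 0.336 with an estimated correlation. The edgeR test called 0 genes, 995 had an unadjusted p under 0.05, DESeq2 called 146, voom with quality weights 50 and limma on deposited RPKM 1. The edgeR count was 20 without library 3, 8 without combination library 4 and 1 without anti-CD40 library 2 or combination library 2.

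After anti-CSF-1R alone, type I interferon genes rose in TAM as well. The list had a median of 0.63 with all 28 members positive (adjusted p = 5.97e-23, and adjusted p = 0.0308 with an estimated correlation), though 0 members passed over all genes and 1 adjusted over the list alone. Cmpk2, an interferon-induced kinase, had 17.8 ± 6.25 CPM against 5.80 ± 0.985 in IgG (log2 change 1.62 ± 0.35, adjusted p = 1), and Rsad2 191 ± 26.5 against 97.6 ± 26.2 (adjusted p = 1). Cholesterol efflux and LXR target genes rose (median 0.24, 0 of 15 over all genes and 0 adjusted over the list alone, adjusted p = 0.0308 with an estimated correlation). B cell genes did too (median 0.73, also with a member without reads at its bound, 0 of 6 over all genes and 0 adjusted over the list alone, adjusted p = 0.0308 with an estimated correlation). Of the 12 lists called in this contrast, 3 were kept with an estimated correlation and 1 was also called by fry. Over all genes tested 1.935% did not overlap between the groups, against 2.857% by chance. TAM IgG 1, rich in ribosomal RNA, held the LXR target Abcg1 at 112 CPM against 355.5 to 434.4 CPM in the other TAM IgG libraries. Without it the LXR median was 0.19 (adjusted p = 0.0408) and the B cell median 1.43 (0.000168), and the latter was 1.13 without TAM IgG 3, 1.12 without TAM IgG 4 and 0.34 with the title code form as a covariate. Without TAM IgG 1, alternative activation (-0.31, adjusted p = 8.19e-05) and cholesterol synthesis genes (-0.25, 0.000764) were called downward with the preset correlation. The edgeR test called 0 genes, and 448 of 17571 had an unadjusted p under 0.05, a smaller share than the 0.05 that chance alone gives. DESeq2 called 5, and voom and limma on RPKM called 0. The edgeR count was 1 without anti-CD40 library 2.

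Set against anti-CSF-1R alone, the combination shows what anti-CD40 added in TAM, and maturation genes again stood among the called genes. Ccl22 rose by 9.23 ± 1.34 (adjusted p = 0.00532), the amino acid oxidase Il4i1 by 8.38 ± 1.53 (adjusted p = 0.0161), Ccr7 by 8.16 ± 1.29 (adjusted p = 0.00942) and Il12b by 7.55 ± 1.13 (adjusted p = 0.00633). The protein C receptor Procr rose by 4.56 ± 0.67 (adjusted p = 0.00532). The selenium carrier Selenop fell by 2.78 (SE 0.51, adjusted p = 0.0162), the leukemia inhibitory factor receptor Lifr by 2.21 (SE 0.38, adjusted p = 0.0131) and Slc9a9 by 2.19 (SE 0.36, adjusted p = 0.0116). All 4 libraries of one treatment lay on one side of the other for each of these genes, which the naming rule asks of genes of largest change. Over all genes tested 5.708% were so separated, against 2.857% by chance. In this contrast 118 of 17571 passed, 82 higher and 36 lower. Glycolysis and hypoxia genes rose (median 0.79, 0 of 23 over all genes and 16 adjusted over the list alone, adjusted p = 0.0209 with an estimated correlation), as did oxidative stress genes (0.58, 1 of 15 and 1 adjusted over the list alone, adjusted p = 0.0209 with an estimated correlation). T and NK cell genes rose (1.01, 2 of 23 and 13 adjusted over the list alone, adjusted p = 0.0254 with an estimated correlation), and alternative activation genes fell (-1.07, 3 of 18 and 5 adjusted over the list alone, adjusted p = 0.0254 with an estimated correlation). Costimulation and maturation genes (1.59, 4 of 17 and 9 adjusted over the list alone) were called and lost at adjusted p = 0.0630 with an estimated correlation.

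Single libraries moved that count of 118. It was 18, 14, 54 and 50 without anti-CSF-1R library 1, 2, 3 and 4, and 19, 54, 28 and 342 without combination library 1, 2, 3 and 4. It was 68 without TAM IgG 2, 77 without TAM IgG 3, 75 without anti-CD40 library 1 and 233 without anti-CD40 library 3. DESeq2 called 540 genes and voom 1112. Il4i1 lost its call without any 1 of the anti-CSF-1R libraries (adjusted p = 0.0652 to 0.0752) and without combination library 1 (0.0504), where Slc9a9 (0.0504) and Selenop (0.0786) were lost too. Selenop was also lost without anti-CSF-1R library 1 (0.0523) and combination library 2 (0.0534) or 3 (0.0730). Lifr was lost without anti-CSF-1R library 1 (0.0511) or 2 (0.0522) and combination library 3 (0.0633), and Ccr7 without anti-CSF-1R library 2 (0.0522). Ccl22, Il12b and Procr passed in all 16 fits that left out a library.

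Set against anti-CD40 alone, the combination shows what anti-CSF-1R added, and neither this contrast nor the interaction of the antibodies gave a called gene in TAM. Combination libraries held Il12b at 2651 ± 2119 CPM against 252 ± 179 CPM after anti-CD40 alone (log2 change 3.40 ± 0.93, adjusted p = 0.758), and Gzmb at 95.9 ± 35.3 against 32.5 ± 9.42 CPM (1.56 ± 0.34, adjusted p = 0.758). T and NK cell genes (median 0.93, 0 of 23 over all genes and 9 adjusted over the list alone) were called and lost at adjusted p = 0.180 with an estimated correlation. Costimulation and maturation genes had an interaction median of 0.92 (0 of 17 and 0 adjusted over the list alone), called and lost at adjusted p = 0.369 with an estimated correlation. In each of these contrasts 14 lists were called and 0 were kept with an estimated correlation. For the combination against anti-CD40, edgeR called 0 genes, 1055 had an unadjusted p under 0.05, DESeq2 called 13, voom and limma on RPKM 0, and edgeR 22 without combination library 4. For the interaction, edgeR called 0 genes, and 453 of 17571 had an unadjusted p under 0.05, a smaller share than the 0.05 that chance alone gives. There DESeq2 called 1, and voom and limma on RPKM 0.

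In MDSC, alternative activation genes fell after both antibodies. Mrc1 fell from 80.0 ± 40.6 to 5.16 ± 3.29 CPM (log2 change -3.95 ± 0.56, adjusted p = 0.0209), lower in 4 of 4 libraries. Groups did not overlap in 3.832% of all genes tested, against 2.857% by chance. The alternative activation list fell too (1 of 18, 8 adjusted over the list alone, median -1.36, adjusted p = 0.00522 with an estimated correlation). The arginase Arg1 stood at 297 ± 102 against 979 ± 292 CPM (adjusted p = 0.0886), and Ccl5 at 3511 ± 2901 against 354 ± 129 CPM (adjusted p = 0.0835). The other called genes had no reads in the IgG libraries and were chosen after their values were seen. They were the latent TGF-beta binding protein Ltbp2 (97.28-fold higher against the floor of 3 reads per library), 1700028J19Rik (18.63-fold), Ahrr (13.69-fold) and the protocadherin Pcdhb5 (10.05-fold). Each had reads in 4 of 4 combination libraries. Together 5 of 17798 genes passed, 4 higher and 1 lower. Type I interferon genes (median 1.28, 0 of 28 over all genes and 22 adjusted over the list alone), T and NK cell genes (1.26, 0 of 23 and 6 alone) and costimulation genes (1.27, also with a member without reads at its bound, 0 of 17 and 4 alone) were called and lost at adjusted p = 0.0936, 0.143 and 0.256 with an estimated correlation. Mature macrophage genes (-0.75, 0 of 21 and 6 alone) and dendritic cell genes (-0.93, 0 of 15, with 1 higher and 2 lower alone) were called and lost at adjusted p = 0.0556 and 0.205 with an estimated correlation. Ly6c2 stood at 35.8 and 48.6 CPM in MDSC IgG 1 and 2, and without these libraries 0 genes passed, with Mrc1 at adjusted p = 0.124. The interferon median was then 0.80 (adjusted p = 8.59e-08), and the dendritic cell call was lost (median -0.11, adjusted p = 0.604). Fitted with the IgG and combination libraries alone, edgeR called 0 genes. With all MDSC libraries 1946 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 459, voom 0 and limma on RPKM 15.

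The MDSC count of 5 against IgG moved with single libraries. It was 0 without MDSC IgG 2, 1 without combination library 2, 11 without anti-CD40 library 3, 24 without MDSC IgG 4 and 155 without combination library 4. It was 2 without MDSC IgG 3, anti-CSF-1R library 2, anti-CD40 library 1 or 2, or combination library 1, and 3 without MDSC IgG 1, anti-CSF-1R library 4, anti-CD40 library 4 or combination library 3. Mrc1 lost its call without MDSC IgG 2 (adjusted p = 0.0929) and without combination library 1 (0.0565), 2 (0.0916) or 3 (0.0796). Ltbp2 was lost without MDSC IgG 2 (0.0652). Ahrr was lost without MDSC IgG 2 or 3, anti-CSF-1R library 2, anti-CD40 library 1 or 2 or combination library 2 (0.0517 to 0.0976). Pcdhb5 was lost without MDSC IgG 1, 2 or 3, anti-CSF-1R library 2 or 4, anti-CD40 library 1, 2 or 4, or combination library 1, 2 or 3 (0.0516 to 0.128). The call of 1700028J19Rik was lost without MDSC IgG 1, 2 or 3, anti-CSF-1R library 1, 2 or 4, anti-CD40 library 1, 2 or 4, or combination library 1 or 2 (0.0527 to 0.145).

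After anti-CD40 alone, MDSC held Mrc1 at 12.8 ± 7.69 CPM against 80.0 ± 40.6 in IgG (log2 change -2.64 ± 0.53, adjusted p = 0.153), and after anti-CSF-1R alone at 25.04 ± 10.98 CPM (-1.68 ± 0.51, adjusted p = 0.483). The 2 genes called after anti-CD40 were Ltbp2 (50.75-fold higher against the floor of 3 reads per library) and Ahrr (11.57-fold). The 2 called after anti-CSF-1R were Ahrr (12.74-fold) and Pcdhb5 (12.58-fold). All had no reads in IgG and were chosen after their values were seen. Type I interferon genes had a median of 1.02 after anti-CD40 (0 of 28 over all genes and 17 adjusted over the list alone) and 0.66 after anti-CSF-1R (0 of 28 and 0 alone), called and lost at adjusted p = 0.291 and 0.435 with an estimated correlation. Without the MDSC IgG libraries of low Ly6c2 the interferon median was 0.65 after anti-CD40 (adjusted p = 4.16e-07) and 0.23 after anti-CSF-1R (adjusted p = 0.437, and 0.40 without MDSC IgG 1 alone), and 0 genes passed in either comparison. Proliferation genes had a median of -0.93 after anti-CD40 (0 of 30 and 7 adjusted over the list alone, adjusted p = 0.291 with an estimated correlation). For anti-CD40 the count was 17 without MDSC IgG 4, 6 without combination library 1, 5 without combination library 4, 2 without anti-CD40 library 3, 1 without anti-CSF-1R library 1 or 4 or combination library 3, and 0 without any other library. For anti-CSF-1R it was 22 without MDSC IgG 4, 1 without anti-CD40 library 3 and 0 without any other library. Ahrr and Pcdhb5 were lost after anti-CSF-1R without any 1 library other than MDSC IgG 4 (adjusted p = 0.053 to 0.185). After anti-CD40, Ahrr was lost without any 1 library other than MDSC IgG 4 and combination library 1 or 4 (0.0579 to 0.190), and Ltbp2 without MDSC IgG 1, 2 or 3, anti-CSF-1R library 2 or 3, anti-CD40 library 1, 2 or 4, or combination library 2 (0.0559 to 0.150). DESeq2 called 473 genes after anti-CD40 and 88 after anti-CSF-1R.

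Between treatments in MDSC, transferrin was lower after both antibodies than after anti-CSF-1R alone. Trf fell from 83.8 ± 38.0 to 11.8 ± 4.63 CPM (log2 change -2.83 ± 0.41, adjusted p = 0.0432). It was lower in 4 of 4 libraries, which the naming rule asks of genes of largest change. Groups did not overlap in 7.933% of all genes tested, against 2.857% by chance. In this contrast 2 genes of 17798 were called, both lower. Trf kept its call without MDSC IgG 1 or 4, anti-CD40 library 3 or combination library 1 or 4, and lost it without any other library (adjusted p = 0.0553 to 0.202). Immediate early genes fell in that comparison (median -0.72, 0 of 22 over all genes and 1 adjusted over the list alone, adjusted p = 0.0469 with an estimated correlation). Against anti-CD40 alone, the combination held Arg1 at 297 ± 102 against 872 ± 314 CPM (-1.56 ± 0.32, adjusted p = 0.406). Alternative activation genes (median -1.06, 0 of 18 over all genes and 2 adjusted over the list alone) and mature macrophage genes (-0.82, 0 of 21 and 8 alone) fell there as lists (adjusted p = 0.0404 in each with an estimated correlation), the former with a median of -0.63 without anti-CD40 library 3. In that contrast edgeR called 0 genes, 1380 had an unadjusted p under 0.05, DESeq2 called 134, voom 2231 and limma on RPKM 0, and edgeR 1 without combination library 4. For the interaction edgeR called 0 genes, 1009 had an unadjusted p under 0.05, DESeq2 called 20, and voom and limma on RPKM 0. The count of 2 against anti-CSF-1R was 117 without MDSC IgG 1, 153 without MDSC IgG 1 and 2 (Ly6c2 at 35.8 and 48.6 CPM), 83 without combination library 4, 39 without anti-CD40 library 3, 17 without combination library 1, 2 without MDSC IgG 4 and 0 without any other library. DESeq2 called 362 genes there and voom 990.

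The difference between TAM and MDSC in the response to each treatment was tested directly, with all libraries taken as independent, since the labels do not say whether TAM and MDSC came from the same tumors. Ahrr passed in all 3 tests, with fitted log2 differences of -7.90 ± 1.12, -9.12 ± 1.13 and -8.72 ± 1.12 for anti-CSF-1R, anti-CD40 and both (adjusted p = 0.003, 0.000235 and 0.000533), and was the 1 gene called in each. It had no reads in the MDSC IgG libraries, so these sizes depend on the prior count, and it was chosen after its values were seen. It averaged 2.57 ± 1.03 CPM in TAM IgG. The 3 tests share the same IgG libraries, so they are not independent results. By voom the adjusted p values were 0.229, 0.0639 and 0.135. By limma on RPKM the differences were 0.03, -0.23 and -0.17, and no call was kept. The log2(RPKM + 1) scale shrinks differences of genes with few reads, so these values cannot decide on Ahrr. With only the groups compared Ahrr was lost for anti-CSF-1R (adjusted p = 0.128) and both (0.202). Without the MDSC IgG libraries of low Ly6c2 it was lost for anti-CSF-1R (0.0917). Without MDSC IgG 4 the counts were 8, 8 and 9. For dendritic cell genes the difference in response to both antibodies, TAM minus MDSC, had a median of 0.91 (0 of 15 over all genes and 2 adjusted over the list alone, adjusted p = 0.046 with an estimated correlation). The list was not called in TAM (median 0.28, or 0.38 with a member without reads at its bound, adjusted p = 0.317) and had a median of -0.93 in MDSC. Without the MDSC IgG libraries of low Ly6c2 the difference was 0.36 and its call was lost (adjusted p = 0.0536). For T and NK cell genes the difference in response to anti-CD40 was -0.93 (0 of 23 and 0 adjusted over the list alone, adjusted p = 1.76e-08), with a median of 0.24 in TAM and 1.05 in MDSC. It was -0.42 without those libraries (adjusted p = 0.0469) and was lost at adjusted p = 0.504 with an estimated correlation. Without them the difference for type I interferon genes, not called with them, was called with the preset correlation for anti-CSF-1R (0.51, adjusted p = 2.93e-05), anti-CD40 (0.32, 0.024) and both (0.43, 0.00246).

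In whole tumors, Lyve1, the hyaluronan receptor of lymphatic endothelium and of a macrophage subset, was lower after anti-CSF-1R. Lyve1 fell from 6.83 ± 2.02 to 0.266 ± 0.192 CPM (log2 change -4.68 ± 0.53, adjusted p = 0.0401), lower in 4 of 4 libraries, and was the 1 gene of 17683 to pass. Groups did not overlap in 1.736% of all genes tested, against 2.857% by chance. Arg1 stood at 130 ± 22.0 against 249 ± 28.04 CPM (-0.93 ± 0.18, adjusted p = 0.468) and Mrc1 at 43.0 ± 30.7 against 83.9 ± 13.7 CPM (adjusted p = 1). Alternative activation genes (median -0.89, 1 of 18 over all genes and 5 adjusted over the list alone) and type I interferon genes (median 0.46, all 28 positive, 0 of 28 and 0 adjusted over the list alone) were called and lost at adjusted p = 0.0621 and 0.112 with an estimated correlation. Mature macrophage genes (-0.35, 0 of 21 and 0 alone), epithelial tumor cell genes (-0.51, 0 of 13 and 2 lower alone) and T and NK cell genes (-0.18, 0 of 23 and 0 alone) were called and lost at adjusted p = 0.252, 0.252 and 0.637 with an estimated correlation. The Lyve1 call was kept without anti-CSF-1R library 2 and lost without each of the other 7 libraries, at adjusted p of 0.0513 to 0.252, and with voom (adjusted p = 0.108). All 4 IgG libraries and anti-CSF-1R library 4 carried the N form of title code, so no comparison within a form had replicates in both groups. With that form as a covariate 1211 genes were called, on a contrast that rests on this 1 library.

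**Figure D3:**
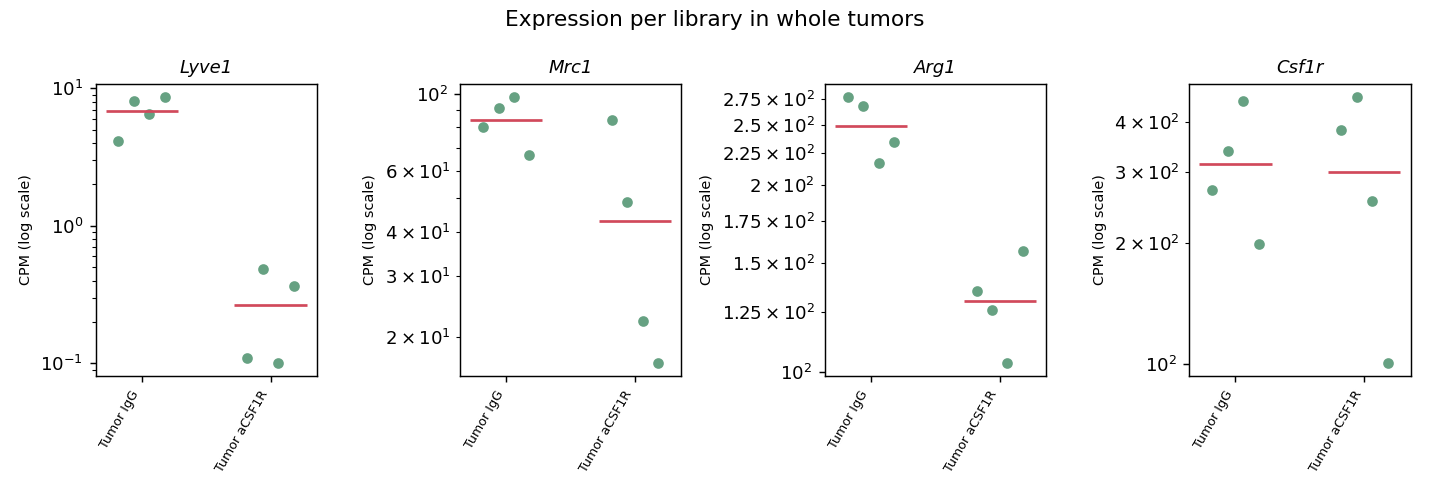
CPM on a log scale of Lyve1, Mrc1, Arg1 and Csf1r in each whole tumor library after IgG or anti-CSF-1R, with bars at the arithmetic mean of 4 libraries. Lyve1 lies between 4.12 and 8.66 CPM in the IgG libraries and between 0.101 and 0.487 CPM in the anti-CSF-1R libraries.

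Over all 17 contrasts, 196 list calls were made with the preset correlation, 22 of them also with an estimated correlation and 37 also by fry. The map of list medians shows these by comparison.

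**Figure D4:**
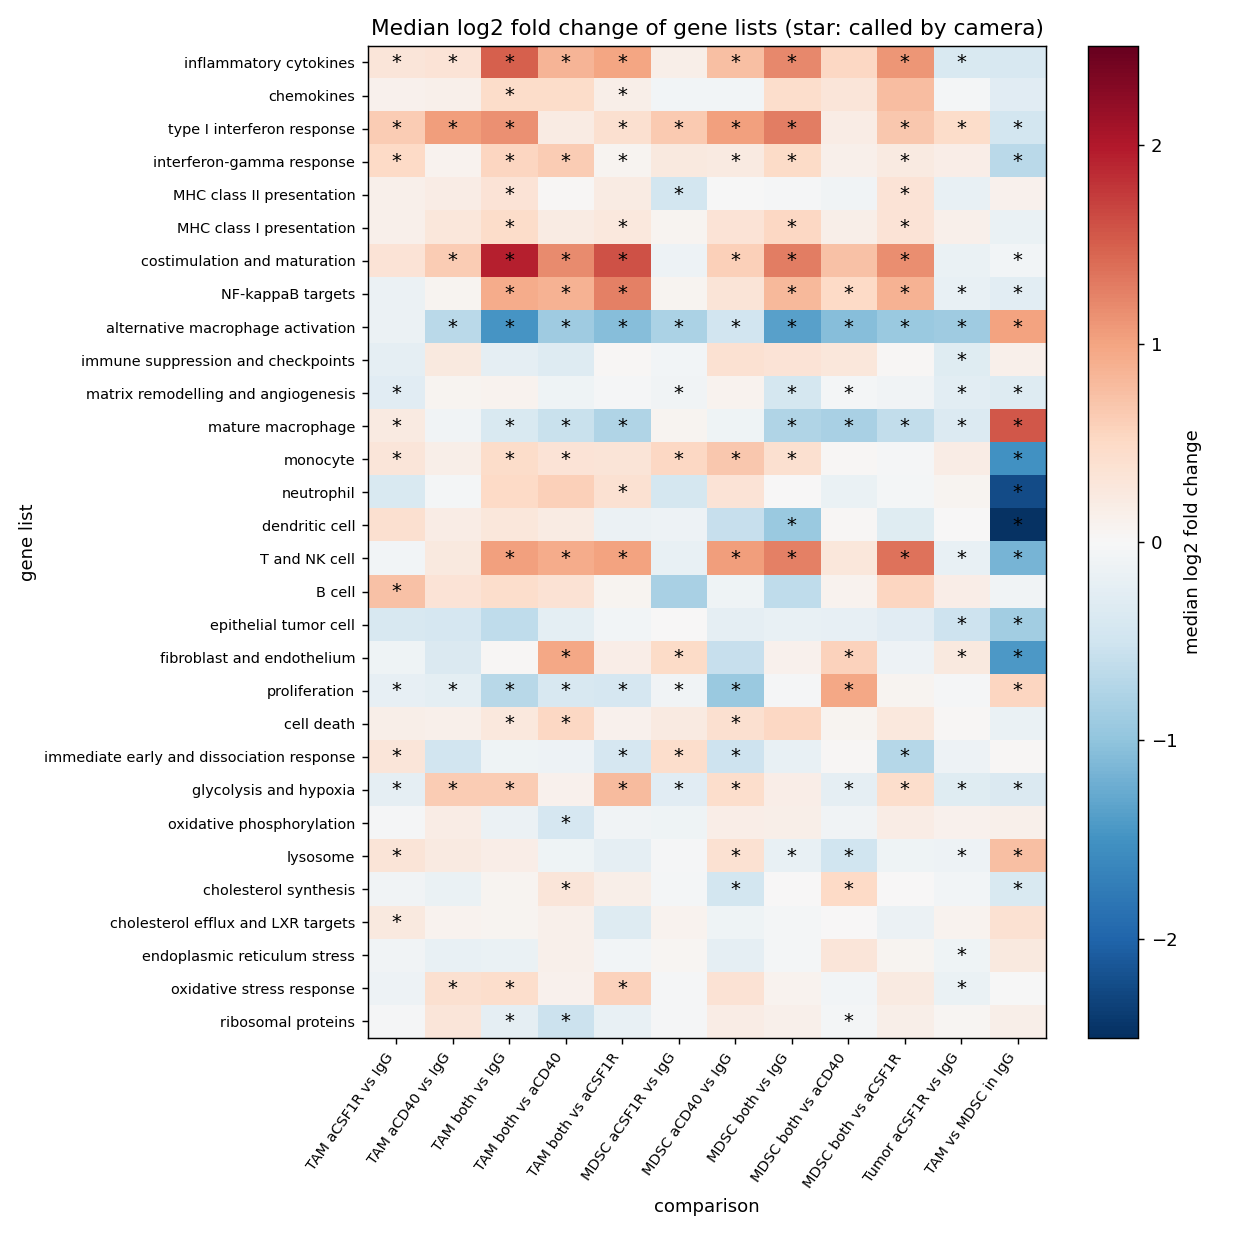
Median log2 fold change of each gene list (vertical axis) in each of 12 comparisons (horizontal axis), on a color scale from blue (lower) to red (higher), with a star where camera's test with a preset correlation called the list. Costimulation and maturation genes have a median of 1.94 in TAM after both antibodies against IgG, and alternative macrophage activation genes -1.48.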

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

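The tests of T and NK cell genes, of dendritic cells in either sort, and of TAM or ribosomal RNA as the source of low Ly6c2 were chosen only after the result was seen, as were the division of the interferon test of the title code form by sample kind and the tests without MDSC IgG 1 and 2 or without the libraries rich in ribosomal RNA. Setting the splits beside the counts without single libraries was likewise chosen only after both were seen. SE values of list medians in this part come from resampling the genes of a list. They hold no spread between libraries and take the genes as independent. Values far from the rest of their group were found in 27 of 232 groups of 4 libraries tested with Dixon's test, and chance alone gives about 1 in 20, or 11.6.

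In TAM, the costimulation and maturation list rose after both antibodies by a median log2 change of 1.94. The form of the title code is argued against as the whole source, since the median was 2.33 with that form as a covariate. Dendritic cells within the sort stay open. The dendritic cell list lay below the maturation list by 1.67 on the log2 scale (difference -1.67, bootstrap SE 0.7), but it holds none of the called maturation genes, so this value decides nothing. The treatment itself also stays open, as the biological explanation the design names, and combination library 4 held far less Ccl22 (46.14 CPM against 1581 to 2991) than the other 3.

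Type I interferon genes had positive medians after anti-CSF-1R in TAM (0.63), MDSC (0.66) and whole tumors (0.46). With the title code form as a covariate the list was called upward in 2 of 2 sorted populations, which argues against that form in TAM. In MDSC only anti-CSF-1R library 2 shared the form that all IgG libraries carried, so the form stays open there. Without the libraries rich in ribosomal RNA the list was called with the preset correlation in 2 of 2 sorted populations, which argues against them in TAM. In MDSC the median was smaller without MDSC IgG 1, as given above, so that library stays open there. In whole tumors the form and the treatment cannot be told apart, because the median of 0.80 with that covariate rests on 1 library, anti-CSF-1R library 4. In MDSC the call was lost without MDSC IgG 1 and 2 (median 0.23, adjusted p = 0.437), so for MDSC the state of those libraries could account for it. The treatment stays open as the biological explanation, with the call kept under an estimated correlation in TAM (adjusted p = 0.0308) and lost in MDSC (0.435) and whole tumors (0.112).

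The libraries labelled MDSC IgG 1 and 2 held Ly6c2 at 35.8 and 48.61 CPM, against 1582 and 1272 CPM in MDSC IgG 3 and 4. A TAM library, or TAM in the sort as the main content, is argued against by the mature macrophage genes. The higher of the 2 libraries' medians lay at -1.35 log2 CPM (SE 0.14 over genes) from that of TAM IgG. MDSC IgG 3 and 4 lay at -1.47 and -1.66. Ribosomal RNA content is argued against, because MDSC IgG 2 held 1.094% such reads, below the 2.11% of MDSC combination library 1, where Ly6c2 stood at 10450 CPM. Dendritic cells in the sort stay open, since the median of dendritic cell genes, relative to the MDSC libraries of treated mice, was -0.38 log2 CPM (SE 1.73) in MDSC IgG 1 and 1.00 (SE 0.48) in MDSC IgG 2, the highest of the 16 MDSC libraries. A wrong label or another sort gate stays open as well, and no biological explanation was tested.

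For T and NK cell genes in TAM after both antibodies, T-lineage genes changed by -1.07 (SE 0.2 over genes) relative to cytotoxic genes. This ran from -1.22 to -0.85 over the 29 settings run for TAM, which share most libraries and are not independent. Neutrophil, B cell and stromal genes changed by -0.96 (SE 0.29) relative to T and NK cell genes, but by -0.27 (SE 0.28) without TAM IgG 1, and the value lay below 0 by over 2 SE in 22 of the 29 settings.

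Library measures of single libraries stood apart from the rest of their group. In units of 1e6 unique reads, TAM IgG 1 held 33.1 (others 56.51 to 58.91), MDSC IgG 1 held 32.44 (55.77 to 58.79) and MDSC anti-CSF-1R library 2 held 60.02 (46.71 to 47.8). The share of reads in the 10 most abundant genes was 30.17% in TAM IgG 1 (others 14.08 to 16.18) and 46.72% in MDSC IgG 1 (10.26 to 12.79). Ribosomal RNA took 12.02% of reads in TAM IgG 1 (others 0.722 to 1.016), 31.88% in MDSC IgG 1 (0.463 to 1.094) and 2.11% in MDSC combination library 1 (0.271 to 0.582).

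In TAM IgG 1, macrophage genes lay below the other TAM IgG libraries in CPM, with Fcrls at 173.5 (others 581.7 to 727.8), C1qc at 515.7 (1116 to 1198), Cd81 at 336.4 (1095 to 1278), Folr2 at 20.21 (54.15 to 60.9), Adgre1 at 251.2 (1215 to 1374), Csf1r at 439.1 (1651 to 1965) and Abcg1 at 112 (355.5 to 434.4). In TAM combination library 4, Ccr7 stood at 73.38 CPM (others 3034 to 3801), Mmp25 at 14.08 (211.9 to 346.6), Ccl5 at 1086 (4086 to 5188), Traf1 at 79.76 (493.1 to 606.5), Rsad2 at 157.5 (399.2 to 475.7), Il4i1 at 4.107 (618.3 to 832.9) and Procr at 36.03 (226.1 to 325.9). In TAM anti-CD40 library 3, Il12b stood at 9.27 CPM (others 234.7 to 422.2) and Ccl22 at 2.966 (192.6 to 364.9). Ccr7 in TAM anti-CSF-1R library 4 was 5.872 CPM (others 9.605 to 10.58), and Hpgds in MDSC IgG 2 was 64.79 CPM (25.21 to 29.52).

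The response differed between TAM and MDSC in the test of the difference itself for Ahrr, at -7.9 for anti-CSF-1R, -9.12 for anti-CD40 and -8.72 for both. Among lists, with the median log2 difference (TAM response minus MDSC response), the response to anti-CSF-1R differed for MHC class II presentation (0.57), costimulation and maturation (0.36), mature macrophage (0.26), monocyte (-0.37), dendritic cell (0.62), B cell (1.19), fibroblast and endothelium (-0.3) and lysosome (0.32), each lost at adjusted p = 0.352 to 0.704 with an estimated correlation. The response to anti-CD40 differed for monocyte (-0.47), dendritic cell (0.82), T and NK cell (-0.93) and proliferation (0.67), each lost at adjusted p = 0.504 to 0.746 with an estimated correlation. The response to both differed for dendritic cell (0.91, kept at adjusted p = 0.046 with an estimated correlation). It also differed for MHC class II presentation (0.32), costimulation and maturation (0.7), matrix remodelling and angiogenesis (0.18), mature macrophage (0.1), proliferation (-0.62), glycolysis and hypoxia (0.49), lysosome (0.29) and oxidative stress (0.42), each lost at adjusted p = 0.297 to 0.533 with an estimated correlation. Without MDSC IgG 1 and 2, 3 of the 8 list calls for anti-CSF-1R, 2 of the 4 for anti-CD40 and 4 of the 9 for both were kept, 5, 4 and 4 other lists gained a call, and the dendritic cell call was lost in each (median -0.31, 0.23 and 0.36, adjusted p = 0.532, 0.425 and 0.0536, with the first median negative although its test pointed upward). Without the libraries rich in ribosomal RNA, 4 of the 8, 3 of the 4 and 4 of the 9 were kept, and 2, 1 and 1 other lists gained a call.

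Other splits of the same samples into groups of the same size were counted for each contrast. The real split gave the highest count in 7 contrasts, at 1 of 35 splits, the smallest share such splits can give, and 17 contrasts were examined. For TAM after both antibodies against anti-CSF-1R the real count was 118 (1 of 35, highest other 2). Without single libraries that count ran from 14 to 342. With 17 contrasts examined, a share of 1 of 35 does not by itself exclude chance. In the other 6 contrasts the count fell to or below the highest other split without some single library, though such fits hold 1 library fewer than the splits. The splits are not taken to exclude chance in these 6 contrasts either. These were 117 genes in TAM after both against IgG (1 of 35, highest other 42, 0 to 565 without single libraries) and 131 between TAM and MDSC (1 of 35, highest other 110, 38 to 229). The highest other split of the latter joins IgG 1 and 2 of both populations, and 23 of its other splits gave calls, which points to a structure of the samples. In MDSC they were 2 genes after anti-CSF-1R (1 of 35, highest other 1, 0 to 22), 2 after anti-CD40 (1 of 35, highest other 1, 0 to 17) and 5 after both against IgG (1 of 35, highest other 4, 0 to 155). The last was 2 in MDSC after both against anti-CSF-1R (1 of 35, highest other 0, 0 to 117). Chance cannot be excluded for the real count of 1 in whole tumors (2 of 35). There the split of IgG 1, 2 and 4 with anti-CSF-1R library 4 gave 222, which points to a structure of the samples that follows the title code form in part, and with that form as a covariate 1211 genes were called. Nor can it be for the differences in response, with 1 gene each, to anti-CSF-1R (4 of 40 splits, highest other 152), anti-CD40 (8 of 40, highest other 111) and both (9 of 40, highest other 346), where the large counts also point to a structure of the samples. The remaining contrasts had a real count of 0, so all splits were as large, 35 of 35 for TAM anti-CSF-1R (highest other 0), anti-CD40 (18) and combination against anti-CD40 (15), 35 of 35 for MDSC combination against anti-CD40 (18), and 100 of 100 for the interactions in TAM (413) and MDSC (38).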

How the results depend on the processing

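The tests without libraries rich in ribosomal RNA or of low Ly6c2, on halved counts, on counts with shared reads and on protein-coding genes, and the list tests without single libraries, were chosen only after the data were seen, and all others were planned. Of the counts of called genes, 125 stayed within 1.5 times under other settings and 85 did not, and without single libraries 226 did and 102 did not. A count of 0 that stayed 0 was scored as unmoved, so contrasts without called genes raise the unmoved tallies. The count of 117 in TAM after both antibodies against IgG ran from 0 to 565 without single libraries. Named genes kept direction and side of the threshold in 1312 cases, lost the call in 133, gained it in 39 and changed sign in 10. Without single libraries these cases were 1935, 371, 12 and 10. The causes were not tested. Depth limits the genes of few reads, such as Ahrr, Pcdhb5 and 1700028J19Rik, and the filter of 5 CPM took such genes out of the test. No paired analysis was run, because the labels give no replicate numbers shared across groups. If TAM and MDSC libraries share a source, the joint fits leave that out. No fit failed, and only the groups compared is the fit as reported for whole tumors and the interactions.

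DESeq2 called 5, 146, 544, 13, 540 and 1 genes in TAM for anti-CSF-1R, anti-CD40 and both against IgG, both against anti-CD40, both against anti-CSF-1R and the interaction. In MDSC it called 88, 473, 459, 134, 362 and 20 in the same order, in whole tumors 29, between TAM and MDSC 615, and for the differences in response to anti-CSF-1R, anti-CD40 and both 37, 69 and 44. Voom with quality weights called 50 after anti-CD40, 1372 after both and 1112 for both against anti-CSF-1R in TAM, and 0 after anti-CSF-1R, 35 after anti-CD40, 0 after both, 2231 against anti-CD40 and 990 against anti-CSF-1R in MDSC. It called 4 in whole tumors, 642 between TAM and MDSC and 0 for the responses to anti-CD40 and to both. Limma on RPKM called 1 gene in TAM after anti-CD40, 0, 0 and 15 in MDSC after anti-CSF-1R, anti-CD40 and both, 207 between TAM and MDSC and 0 for each difference in response.

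Without a count filter 7, 180 and 1 genes were called in TAM after anti-CD40, after both and for both against anti-CD40, and 1, 10 and 6 in MDSC after anti-CD40, after both and for both against anti-CSF-1R. With the 5 CPM filter MDSC gave 0 after anti-CSF-1R, 0 after anti-CD40, 1 after both and 45 against anti-CSF-1R, whole tumors 0 and each difference in response 0. With the title code form as a covariate TAM gave 3 after anti-CD40 and 209 after both, MDSC 0, 0, 11 and 1 after anti-CSF-1R, anti-CD40, both and both against anti-CSF-1R, and whole tumors 1211. With only the groups compared the counts were 0 in TAM after both, 0, 0, 0 and 20 in MDSC in that order, 1 between TAM and MDSC, and 0 for the responses to anti-CSF-1R and to both. Halved counts gave 0, 0 and 9 in MDSC after anti-CSF-1R, anti-CD40 and both. Counts with shared reads gave 0 for both against anti-CSF-1R in MDSC. Protein-coding genes gave 0, 1, 8 and 16 in MDSC after anti-CSF-1R, anti-CD40, both and both against anti-CSF-1R. Without the libraries rich in ribosomal RNA these were 0, 0, 3 and 117, with 3 for the response to anti-CD40. Without the libraries of low Ly6c2 they were 0, 0, 0 and 153, with 236 between TAM and MDSC and 0 for the response to anti-CSF-1R. For a count of 0 the counts by the other tools are those given here.

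Of 196 list calls, 22 were called with an estimated correlation, and fry called 39 lists in all. Without the libraries rich in ribosomal RNA, the list calls against IgG lost and gained were 4 and 2 in TAM after anti-CSF-1R, 1 and 3 after anti-CD40, 4 and 2 after both, and in MDSC 2 and 1, 1 and 3, and 2 and 0. Without the MDSC IgG libraries of low Ly6c2 they were 6 and 3, 4 and 4, and 5 and 3 in MDSC, and 4 and 3 between TAM and MDSC. In whole tumors 14 list calls became 9 with the title code form as a covariate. Csf1r, not called in any contrast, changed sign in TAM after anti-CD40 with the title code form (0.08), after both without the libraries rich in ribosomal RNA (-0.12), in MDSC after anti-CSF-1R by voom (-0.09), with the title code form (-0.03), without the libraries rich in ribosomal RNA (-0.06) and without those of low Ly6c2 (-0.29), in whole tumors by voom (0.14), and between TAM and MDSC by voom (-0.02) and without the libraries of low Ly6c2 (-0.3). Without single libraries it ran from -0.39 to 0.13 in TAM after anti-CD40 (sign changed without IgG 3 at 0.01, IgG 4 at 0.07 and anti-CD40 library 3 at 0.13) and from -0.13 to 0.42 after both (changed without combination library 2 at -0.13 and IgG 1 at -0.12). It ran from -0.06 (changed without IgG 1) to 0.42 in MDSC after anti-CSF-1R, from -0.34 to 0.24 in whole tumors (changed without IgG 3 at 0.15, anti-CSF-1R library 3 at 0 and library 4 at 0.24), and from -0.1 (changed without MDSC IgG 1) to 0.5 between TAM and MDSC. Ahrr had a difference in response to anti-CSF-1R of 0.03 by limma on RPKM, a scale that shrinks differences of genes with few reads.

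Leaving out 1 library at a time, TAM counts ran from 0 to 1 (anti-CD40 library 2) after anti-CSF-1R, 0 to 20 (anti-CD40 library 3) after anti-CD40, 0 (IgG 4) to 565 (combination library 4) after both, 0 to 22 (combination library 4) for both against anti-CD40, 14 (anti-CSF-1R library 2) to 342 (combination library 4) for both against anti-CSF-1R, and 0 to 0 for the interaction. In MDSC they ran from 0 to 22 (IgG 4), 0 to 17 (IgG 4), 0 (IgG 2) to 155 (combination library 4), 0 to 1 (combination library 4), 0 to 117 (IgG 1) and 0 to 0 in the same order. Whole tumors gave 0 to 1 (anti-CSF-1R library 2), TAM against MDSC 38 (TAM IgG 3) to 229 (MDSC IgG 2), and the differences in response 1 to 8, 1 to 8 and 1 to 9 (MDSC IgG 4 in each). List calls ran from 75 to 91 in the TAM fit, 57 to 72 in the MDSC fit, 9 (anti-CSF-1R library 3) to 16 in whole tumors and 30 to 45 in the joint fit.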

Other observations

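The list tests in this part were set beforehand, and which lists and single libraries are described was chosen only after the result was seen. Proliferation genes stood higher in MDSC after both antibodies than after anti-CD40 alone, with a median log2 change of 0.96 and positive values in 30 of 30 members. Over all genes 0 members passed and 10 did adjusted over the list alone (adjusted p = 3.67e-13 with the preset correlation). The call was lost at adjusted p = 0.276 with an estimated correlation. The interaction of the antibodies had a median of 1.01 for the list with 29 members positive (0 of 30 over all genes and 0 adjusted over the list alone), lost at adjusted p = 0.719 with an estimated correlation. Lysosome genes had a median of -0.49 in the same MDSC contrast (0 of 25 over all genes and 0 adjusted over the list alone, adjusted p = 1.7e-08), lost at adjusted p = 0.128 with an estimated correlation.

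Glycolysis and hypoxia genes had a median of 0.63 in TAM after anti-CD40 alone, with 23 of 23 members positive (0 over all genes and 7 adjusted over the list alone, adjusted p = 2.3e-11). That call was lost at adjusted p = 0.126 with an estimated correlation. In whole tumors after anti-CSF-1R the list had a median of -0.3 (0 of 23 over all genes and 0 adjusted over the list alone, adjusted p = 6.64e-10), lost at adjusted p = 0.146 with an estimated correlation.

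In each group that received anti-CD40, 1 library held less Il12b, Ccl22 and Ccr7 than the other 3. TAM anti-CD40 library 3 had Ccr7 at 5.35 CPM against 269.7 to 928.4 CPM. In TAM combination library 4 Il12b stood at 93.95 CPM against 2434 to 5270. MDSC anti-CD40 library 3 had Il12b at 4.345 CPM (others 66.48 to 150.5), Ccl22 at 5.422 (90.96 to 249.8) and Ccr7 at 17.49 (197 to 769.4). MDSC combination library 4 had Il12b at 45.77 CPM (others 252.4 to 1054), Ccl22 at 45.64 (613 to 1306) and Ccr7 at 113.2 (1420 to 2530). These libraries have the same place in the order of records in TAM and MDSC, as have the IgG libraries rich in ribosomal RNA. The labels do not say whether libraries of TAM and MDSC came from the same mice, so a shared source stays untested.

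The MDSC IgG libraries of low Ly6c2 held other genes at levels unlike MDSC IgG 3 and 4. Ccr7 stood at 461.1 and 287 CPM in MDSC IgG 1 and 2, against 29.08 and 7.611 CPM in MDSC IgG 3 and 4. For Ccl22 these values were 158.3 and 138.8 against 7.003 and 4.828 CPM, for Il12b 98.65 and 45.73 against 8.812 and 1.006 CPM, for Flt3 38.71 and 14.87 against 4.624 and 0.8047 CPM, and for the transcription factor Zbtb46 35.62 and 7.225 against 0.5696 and 0.9052 CPM.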
